A study of Mus musculus with 4 samples.

How the data were processed

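Each of the 4 libraries (Control, Butyrate, B12 and B12+Butyrate) holds CD45.2+ bone marrow cells of 3 mice pooled before loading, so a group is 1 library and the mice cannot be told apart. Per the labels' protocols, live cells were sorted by CD45.2 and Kit, Kit+ and Kit- cells were mixed 50:50, and libraries were made with the 10x Genomics 3' v3.1 kit. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 per the file headers, on genome build GRCm39 per the submitters' processing notes. Whether reads in introns were counted, and whether barcodes were filtered beyond the Cell Ranger call, is not given in the sources used here. Gene identifiers and symbols are those of the files (33696 genes), and no coordinates were used. The design is a factorial of 2 treatments, B12 and butyrate. The groups, comparisons, gene lists, cell type markers, rule for named genes and all but 2 of the alternatives were fixed before the data were examined.

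Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Doublets were called per library by simulating doublets at 2 times the number of cells, scoring each cell by the share of simulated doublets among 50 neighbours and removing the highest-scoring cells at 0.8% per 1000 cells (678, 431, 578 and 492 cells in Control, Butyrate, B12 and B12+Butyrate). Of 34670 barcodes with 449267997 UMIs, 29030 cells remained. UMIs per cell were scaled to 10000 and log-transformed, 2000 variable genes were chosen within 20 bins of mean expression among genes seen in at least 20 cells, values were scaled and clipped at 10, and 30 principal components were taken. The 4 libraries were clustered together without integration, on a graph of neighbours shared among 20 nearest with the Leiden method at resolution 1, which gave 33 clusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.

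Clusters were scored on markers of 20 cell types by the mean z-score of the markers' log2 CPM (pseudocount 10 CPM) across clusters, and took the type with the highest score if it was at least 1.25. At least 3 of its markers had to reach 20 CPM and lie 1 log2 unit above the mean of all clusters. Leading genes are the 10 genes at 100 CPM or more with the highest fold over all other cells pooled. A cluster stayed unnamed when its leading genes held more markers of another lineage than of its own, or when its median UMI count was under 1/3 of its libraries' with no own marker among its leading genes. The comparison with all other cells pooled, the 1.25 limit and the merging of immature with mature neutrophils and of pro/pre-B with B cells into lineage classes were chosen after the clusters were seen. The 5 unnamed clusters had these shares in Control, Butyrate, B12 and B12+Butyrate: 3.13%, 3.87%, 2.03% and 1.90% for number 13 (led by Runx2 and Flt3, nearest to plasmacytoid DC with a score just under the limit), 2.54%, 3.36%, 1.74% and 1.59% for number 15 (Cd209a and C1qa, nearest to macrophages), 2.33%, 2.92%, 1.67% and 1.28% for number 16 (low UMIs, nearest to monocytes), 0.495%, 0.959%, 0.776% and 0.407% for number 25 (Adgre4 and Ace, nearest to monocytes) and 0.124%, 0.330%, 0.0535% and 0.126% for number 30 (Rora and Gata3, nearest to lymphoid-primed progenitors). Among named clusters, neutrophil clusters led by cell cycle genes (Ube2c, Ccne2 and Cenpf) and a monocyte cluster led by the interferon genes Ifit3 and Cxcl10 were kept in their classes. Names rest on these markers alone and are written with the ending -like.

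Shares of cells have exact (Clopper-Pearson) 95% intervals, and ratios of shares have 95% intervals from the normal approximation on the log scale. Myeloid-like classes are neutrophil-like, monocyte-like, GMP-like, conventional-DC-like and basophil-like cells, set against B-lineage-like, plasma-like, T-like and NK-like cells. For genes, UMIs were summed per library and class and divided by the class total (CPM) with exact Poisson 95% intervals, and log2 ratios used a pseudocount of 10 CPM. The floor for a gene with 0 UMIs is 3 counts per class sum. Depth of the class sums ran from 2321535 UMIs (B-lineage-like cells of B12) to 56456882 UMIs (neutrophil-like cells of B12+Butyrate) in the 5 classes given. No test was run between groups. A model with additive effects of both treatments over the 4 libraries would take their interaction as error and was not run.

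A gene list's value is the median log2 ratio of members at 10 CPM or more in either library, with a 95% interval from 1000 Poisson draws of the counts and its place among 10000 random lists of the same size matched on mean expression in 20 bins. That place describes these libraries only. The 27 lists cover inflammation (NF-kB, interferon, MHC class I and II, Toll-like receptors), granules, lineage regulators, HSC identity, cell cycle, one-carbon metabolism, DNA methylation, histone deacetylases, butyrate transport, energy and cholesterol metabolism, stress, p53 targets, haemoglobin and sex-linked genes. Which lists to describe in which class, and which medians to treat as main answers, was chosen after the medians were seen. Named genes are, in each of the 4 classes with most cells in their smallest library and each of the 3 main comparisons, the 3 highest and 3 lowest log2 ratios among genes at 100 CPM or more in 1 library and 50 UMIs over both. Haemoglobin, immunoglobulin and T-cell receptor segments, mitochondrial and ribosomal protein genes, Xist, Y-linked genes and unnamed gene models were left out. The highest and lowest members at 100 CPM or more of described lists are named as examples.

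Correlations across genes used genes at 50 CPM or more in the mean of the libraries. Values for no difference came from 20 sets of Poisson counts around the pooled means. Alternatives were a looser cell filter (200 genes, 500 UMIs, 20% mitochondrial UMIs), a stricter one (1000 genes, 2000 UMIs, 5%), doublets kept, resolutions 0.5 and 2, each library clustered alone, variable genes without cell cycle, haemoglobin, immunoglobulin and sex-linked genes, median-of-ratios size factors over genes at 50 CPM, pseudocount 1, no minimum for list members, cells thinned to 2000 UMIs, class sums standardised to the pooled cluster makeup, and correlations at 100 CPM. Standardised sums weight the CPM of each cluster by its share of cells pooled over the libraries, while class sums weight clusters by UMIs. Values with and without the same makeup therefore differ in this weighting too. The gene steps were tested on simulated counts of B12 against Control. In neutrophil-like cells (22622 genes) and HSC/MPP-like cells (19475 genes) 50 of 50 genes had the right direction at each of 1.25-fold, 1.5-fold, 2-fold and 4-fold. Intervals held the true ratio for 92%, 94%, 98% and 96% of them in neutrophil-like and 98%, 92%, 90% and 100% in HSC/MPP-like cells. The simulated counts follow the Poisson model behind the intervals, so this checks the computation only. It says nothing on differences between mice or libraries. A test on free monocyte RNA set beforehand used the 50 most abundant genes at 20-fold or more in monocyte-like over neutrophil-like cells. It was dropped, since many of them lie near 1 CPM in neutrophil-like cells and their median log2 ratio depended on a pseudocount of 1 CPM (−0.29 and −0.25 with it, −0.42 and −0.51 without it, for Butyrate over Control and B12+Butyrate over B12). Its place was taken by the share of a gene's UMIs in neutrophil-like cells that monocyte RNA would bring at the level of the 8 monocyte markers, their median CPM in neutrophil-like over monocyte-like cells. The tests on the interferon-high cluster and on handling stress were written for both butyrate comparisons together and split by comparison after their values were seen. The bound for handling stress was changed after its values were seen, and is now the interferon median of the same comparison, set against the central 95% of the handling genes. A test on granule RNA in HSC/MPP-like cells was planned and not run.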

Results

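Single-cell RNA was measured in bone marrow of mice that had been lethally irradiated and given equal numbers of CD45.1+ wild-type competitor cells and CD45.2+ cells lacking 1 copy of Tet2. Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA. After 1 month the mice received injections of 0.29 µg vitamin B12 or saline 2 times a week, with 100 mM sodium butyrate or 100 mM sodium chloride in the drinking water, for 7 months. Butyrate is a short-chain fatty acid made by gut bacteria and an inhibitor of histone deacetylases. The 4 groups, called Control, Butyrate, B12 and B12+Butyrate here, each gave 1 library of live CD45.2+ cells pooled from 3 mice, so n = 1 library per group and no difference has a replicate check. Kit+ and Kit- cells were sorted apart and mixed 50:50, which raises the share of progenitors over that of marrow and sets part of every share below.

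The Control, Butyrate, B12 and B12+Butyrate libraries held 9688, 7932, 8980 and 8070 barcodes with 123435815, 95892397, 117318883 and 112620902 UMIs. After filtering and removal of called doublets, 8074, 6362, 7470 and 7124 cells were used, with medians of 10999.5, 11263.5, 12096 and 11845 UMIs per cell. Barcodes above the mitochondrial limit made up 8.89%, 13.9%, 9.43% and 5.34%. Levels are CPM, a gene's UMIs scaled by all UMIs of its cell class in 1 library. Intervals in brackets are exact 95% Poisson intervals for CPM and exact 95% binomial intervals for shares. All intervals here cover counting error only, not differences between mice. Those of CPM and of list medians take the UMIs of a class sum as independent, so they also leave out variation between cells. They are too narrow where few cells carry a gene's UMIs. No test between groups was made, because cells of 1 library are not replicates, and values are given side by side.

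Tet2 (ENSMUSG00000040943) was at 96.6 (94.7 to 98.5) CPM over all cells of Control, 92.3 (90.2 to 94.4) in Butyrate, 79.5 (77.8 to 81.2) in B12 and 77.1 (75.4 to 78.8) in B12+Butyrate. All libraries carry the same genotype by label, and 3' reads outside a deleted part say nothing on the deleted copy. The Tet2 values pool all cells, so they can also shift with the class shares given below. The cells formed 33 clusters, of which 28 were named and grouped into 11 classes. Neutrophil-like cells were the most abundant class in every library, followed in Control by monocyte-like, B-lineage-like, T-like, GMP-like (granulocyte-monocyte progenitor), conventional-DC-like and HSC/MPP-like (stem and multipotent progenitor) cells. No cluster was named erythroid-like or megakaryocyte-like, and Gata1 was at 0.911 CPM or less in every library.

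**Figure D1:**
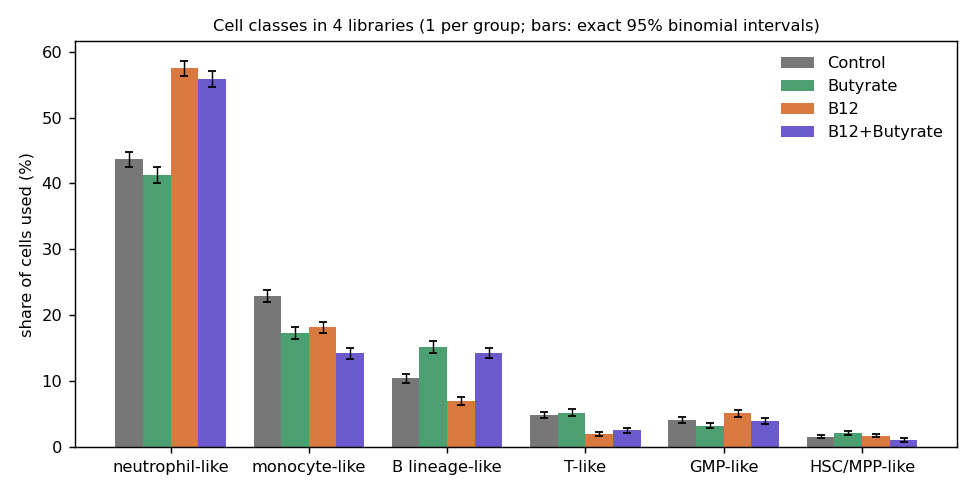
Share of the cells used (%, vertical axis) in 6 classes for the 4 libraries, with exact 95% binomial intervals as bars. Neutrophil-like cells made up 57.5% and 55.8% in the B12 libraries against 43.6% and 41.3% without B12, and T-like cells 1.97% and 2.499% against 4.87% and 5.16%.

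B12 against Control asked what high B12 did to Tet2-deficient blood formation on sodium chloride water, with myeloid bias and inflammation named in the study's title. The myeloid share was higher with B12: myeloid-like classes were 89.7% (89.0 to 90.4%) of myeloid-like plus lymphoid-like cells in B12 and 82.0% (81.1 to 82.9%) in Control. Neutrophil-like cells were 57.5% (56.4 to 58.6%) of all cells against 43.6% (42.6 to 44.7%), a ratio of 1.32 (1.28 to 1.36). T-like cells were 1.97% (1.67 to 2.31%) against 4.87% (4.41 to 5.36%), B-lineage-like cells 6.96% (6.39 to 7.56%) against 10.4% (9.73 to 11.1%) and plasmacytoid-DC-like cells 0.281% (0.174 to 0.429%) against 0.991% (0.786 to 1.23%), or 2.32% against 4.12% with the unnamed cluster nearest to them. In neutrophil-like cells Olfm4, a granule glycoprotein of a neutrophil subset, was at 426 (421 to 431) CPM in B12 and 130.1 (127 to 133) in Control.

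Monocyte-like cells were 18.1% (17.3 to 19.0%) in B12 and 22.9% (22.0 to 23.8%) in Control, and conventional-DC-like cells 0.977% (0.767 to 1.23%) and 1.63% (1.37 to 1.94%). GMP-like cells were 5.09% (4.60 to 5.61%) against 4.03% (3.61 to 4.48%). HSC/MPP-like cells were 1.71% (1.43 to 2.03%) against 1.55% (1.29 to 1.84%) of all cells, and 25.2% against 27.8% of HSC/MPP-like plus GMP-like cells. Those stem cell shares overlapped in their counting intervals, and the log2 ratio of the second was −0.14, or −0.45 at a clustering resolution of 0.5. With each library clustered alone the log2 share ratio of monocyte-like cells was −0.60 in place of −0.34. With a looser cell filter that of B-lineage-like cells was −0.25 in place of −0.58.

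Among neutrophil-like genes, the replication-dependent histone H4c4 (log2 ratio 0.40) and the endoplasmic reticulum chaperone Hspa5 (0.39) were also higher with B12. Mpo, the myeloperoxidase of primary granules, highest in GMP-like cells (−0.60), Suco (−0.43) and Retnlg, a marker of mature neutrophils (−0.36), were lower. Retnlg leads the clusters of mature neutrophils, and its log2 ratio was −0.12 with the same makeup of neutrophil clusters in each library. The primary granule list had a median of −0.17, with 5 of 7 members lower, and the tertiary granule and maturation list −0.08, with 12 of 13 lower. The secondary granule and alarmin list was level at −0.03, between Camp at 0.09 and Ifitm6 at −0.07. The medians of S phase (0.06, 12 of 17 members higher) and G2/M phase (0.06, 16 of 20 higher) were small, and 0.013 and −0.046 with the same makeup of neutrophil clusters.

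In monocyte-like cells the heat shock genes Hspa1b and Hspa1a were higher with B12, at 898 (885 to 911) against 466 (458 to 474) CPM and 749 (737 to 761) against 460.1 (452 to 468) CPM. The serine protease Ctsg (log2 0.66) was higher too, while Chil3 (−0.94), S100a9 (−0.79) and the phosphodiesterase Pde4b (−0.68) were lower. S100a9 and Chil3 were highest in neutrophil-like cells and Ctsg in GMP-like cells (4387 CPM), whose share was higher in B12. All 18 S phase members were higher, with a median of 0.30 (interval 0.29 to 0.37) that lay above all 10000 random lists. Examples are Dut, which removes dUTP (0.63), and the sliding clamp Pcna (0.26). MHC class II presentation had a median of 0.26, with 7 of 7 members higher and H2-Aa at 0.47, but −0.42 at a clustering resolution of 2. Toll-like receptor sensing was at −0.13, with 11 of 13 members lower.

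Inflammatory lists gave no common direction with B12. The NF-kB list had medians of −0.05 in neutrophil-like, −0.06 in monocyte-like, 0.21 in B-lineage-like, −0.02 in GMP-like and −0.11 in HSC/MPP-like cells. With no minimum for list members the B-lineage-like value was −0.032, and the monocyte-like one was 0.023 with the same makeup of monocyte clusters and 0.050 with cells thinned to 2000 UMIs. Tnf, a member, was at 112 CPM in monocyte-like cells of B12 and 67.5 in Control. The interferon response list was at −0.10 (interval −0.12 to −0.04) in monocyte-like cells, with 13 of 21 members lower, and at 0.08 with the same makeup of monocyte clusters. Its medians were −0.07, 0.17, −0.03 and 0.14 in neutrophil-like, B-lineage-like, GMP-like and HSC/MPP-like cells.

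In B-lineage-like cells the germ cell bridge gene Tex14 was at 333 (309.9 to 357) CPM in B12 and 71.4 (63.8 to 79.6) in Control, the histone H2ac6 at 153 (138 to 170.1) and 35.0 (29.8 to 40.9), and Arrdc3 at 127 (113 to 142) and 46.6 (40.5 to 53.3). Apoe (−0.70), Nopchap1 (−0.68) and the interleukin 5 receptor gene Il5ra (−0.68) were lower, though with a looser cell filter Apoe was at 0.19. All 17 measured G2/M members were higher, with a median of 0.67 (interval 0.57 to 0.79). The handling list of immediate early and heat shock genes was at 0.45 (interval 0.41 to 0.50), led by Dnajb1 (0.95). S100a8, a neutrophil RNA, stood in the same cells at 597 (566 to 629) CPM in B12 and 357 (340.2 to 375) in Control.

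In GMP-like cells Hspa1b (log2 0.62), Hspa1a (0.58) and the adhesion receptor Vcam1 (0.55) were higher with B12. Lower were Ltf, lactotransferrin of secondary granules (−0.72), the nuclear RNA Neat1 (−0.65) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (−0.48). The log2 ratio of Ltf, an abundant neutrophil RNA, was −0.36 with doublets kept. The myeloid regulator list was at 0.09 with 9 of 12 members higher, and the unfolded protein response list at −0.10. In HSC/MPP-like cells 8 of 11 HSC identity genes were lower with a median of −0.16 (interval −0.28 to −0.04), among them Meis1 at 378 against 479 CPM. That median was 0.24 at a clustering resolution of 0.5. Medians there were 0.02 for myeloid and −0.03 for lymphoid regulators, with Tcf4 lowest (−0.51), and −0.49 for the secondary granule genes of neutrophils.

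Butyrate against Control gave the butyrate difference without B12. Wfdc17 (ENSMUSG00000069792), a secreted antiprotease-like protein of myeloid cells, was at 25.2 (23.7 to 26.9) CPM in neutrophil-like cells of Butyrate and 108 (105 to 111) in Control. Ifitm1 (ENSMUSG00000025491), an interferon-induced membrane protein, was at 37.6 (35.7 to 39.6) and 135 (132 to 138). In monocyte-like cells the interferon response list had a median of 0.45 (interval 0.37 to 0.47), with 20 of 22 members higher, above all 10000 random lists. The B-lineage-like share was 15.1% (14.2 to 16.0%) in Butyrate and 10.4% (9.73 to 11.1%) in Control.

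**Figure D2:**
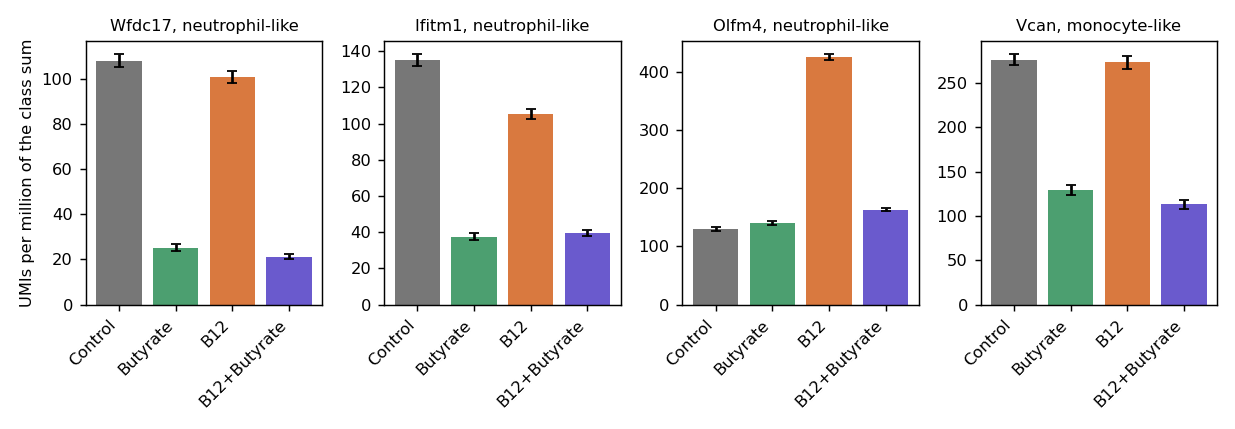
CPM of the class sum (vertical axes, each from 0) of 3 genes in neutrophil-like cells and of Vcan in monocyte-like cells for the 4 libraries, with exact 95% Poisson intervals as bars. Wfdc17, Ifitm1 and Vcan were lower in both butyrate libraries (25.2 and 21.2 CPM for Wfdc17), and Olfm4 was highest in B12 (426 CPM).

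Myeloid-like classes were 75.2% (74.1 to 76.4%) of myeloid-like plus lymphoid-like cells in Butyrate, against 82.0% in Control. Monocyte-like cells were 17.3% (16.4 to 18.2%) against 22.9% (22.0 to 23.8%) and neutrophil-like cells 41.3% (40.0 to 42.5%) against 43.6%. HSC/MPP-like cells were 2.09% (1.75 to 2.47%) against 1.55% (1.29 to 1.84%) of all cells, and 39.2% against 27.8% of HSC/MPP-like plus GMP-like cells. T-like cells were 5.16% (4.62 to 5.73%) against 4.87% (4.41 to 5.36%). The log2 share ratio of monocyte-like cells (−0.41) was −0.12 at a clustering resolution of 2 and −1.22 with each library clustered alone. That of B-lineage-like cells (0.54) was 0.17 with each library clustered alone.

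In neutrophil-like cells Mpo (log2 −0.96) was lower and Cmss1 (0.82), the Mediator kinase gene Cdk8 (0.76) and Lars2 (0.59) were higher with butyrate. The primary granule list had a median of −0.71 (interval −0.74 to −0.67), but 3 of its 7 members were higher and Lyz2, which encodes lysozyme, was at 0.09. Mpo was highest in GMP-like cells (7279 CPM), whose share was 3.24% against 4.03%. Elane, another GMP RNA, was at 235 against 389 CPM in neutrophil-like, 13.1 against 52.5 in B-lineage-like and 12.3 against 62.7 in T-like cells. All 13 tertiary granule and maturation members were lower, with a median of −0.31 and Retnlg at 1836 (1823 to 1849.9) against 3434 (3417 to 3451) CPM. With the same makeup of neutrophil clusters in each library that median was 0.02. Secondary granule genes were at 0.06, NF-kB genes at 0.03 with Nfkbia at 0.26, and interferon genes at −0.07 with Ifitm3 at −0.44. All 17 S phase members were higher, with a median of 0.11, and G2/M phase was at 0.04. With the same makeup these were 0.038 and −0.047.

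In monocyte-like cells Ifi27l2a, an interferon-induced gene, was at 1209 (1191 to 1226) CPM in Butyrate and 643 (633 to 652) in Control. Tex14 (0.81) and Cmss1 (0.68) were higher as well. Wfdc21 (−2.28), the siderophore-binding Lcn2 (−1.58) and the alarmin S100a8 (−1.54) were lower. All 3 were highest in neutrophil-like cells, where Wfdc21 averaged 5163 and Lcn2 13219 CPM over the libraries. MHC class I presentation had a median of 0.08, with 8 of 11 members higher, and MHC class II 0.08. NF-kB genes were at 0.04, Toll-like receptor genes at −0.03, S phase at −0.04 and G2/M phase at −0.06. The handling list was higher in 15 of 16 members, with a median of 0.32 (interval 0.28 to 0.34) and Egr1 at 171 against 104 CPM.

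The handling list was also higher in B-lineage-like (0.32), GMP-like (0.51) and HSC/MPP-like cells (0.26) of Butyrate than of Control. With B12 in both libraries the B-lineage-like median was −0.22, and the other medians were small, as given below. B12 against Control uses the same Control library. Its Hspa1a was the lowest of all libraries in monocyte-like, B-lineage-like and GMP-like cells. Values over Control cannot tell a low Control from a butyrate difference. In B-lineage-like cells Polg2, an accessory subunit of the mitochondrial DNA polymerase (log2 0.90), the nucleolar gene Tcof1 (0.90) and Hspa1a (0.72) were higher. The oestrogen receptor gene Esr1 (−0.64), Cecr2 (−0.63) and Apoe (−0.53) were lower. MHC class II presentation was higher in 9 of 10 members, with a median of 0.13 (interval 0.10 to 0.16) and H2-DMa at 0.24. Interferon genes were at 0.10 and NF-kB genes at 0.06. G2/M genes were at −0.29, but at 0.12 with doublets kept.

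In GMP-like cells Hspa1a was at 446 (429 to 464) CPM in Butyrate and 231 (221 to 241) in Control, and Ly6a2 (0.92) and Rabepk (0.79) were higher. Ltf (−0.73) and the endoplasmic reticulum genes Sdf2l1 (−0.72) and Hsp90b1 (−0.63) were lower. The unfolded protein response list had a median of −0.39 (interval −0.44 to −0.31), although 5 of 13 members were higher. NF-kB genes were higher in 11 of 12 members with a median of 0.28 (interval 0.17 to 0.37), while interferon genes were at −0.04. Myeloid regulators were at 0.13 and at −0.003 with cells thinned to 2000 UMIs. In HSC/MPP-like cells lymphoid regulators were higher in 5 of 7 members with a median of 0.28 (interval 0.20 to 0.51). Dntt, the terminal transferase of early lymphoid cells, was at 108 CPM in Butyrate and 16.8 in Control. HSC identity genes were at 0.06 with Hlf at 0.37, interferon genes at 0.19, NF-kB genes at −0.11 and myeloid regulators at −0.02. Secondary granule genes, which are neutrophil RNAs, were at −1.82 in the same cells.

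**Figure D3:**
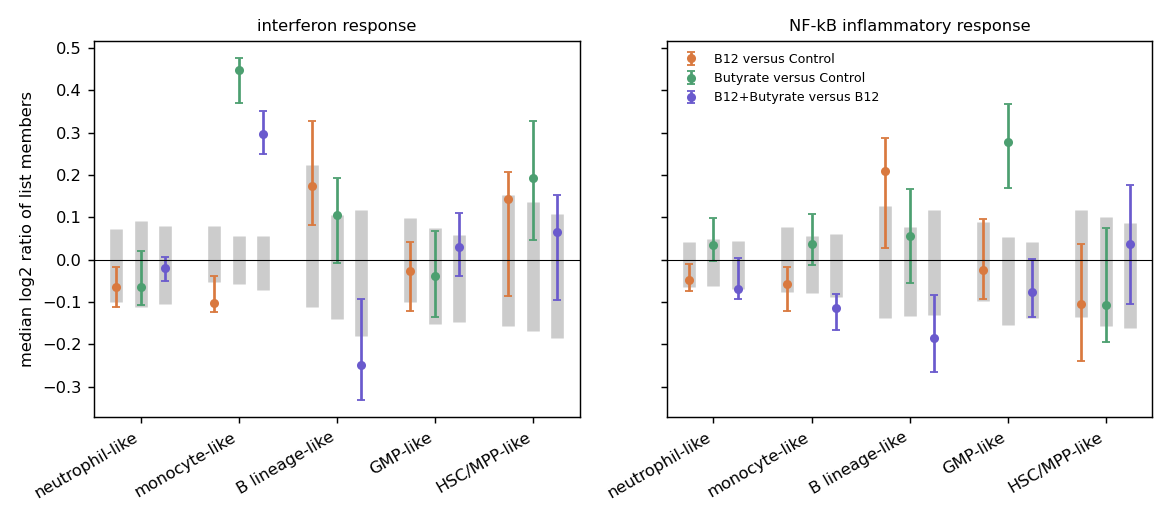
Median log2 ratio (vertical axis) of the interferon and NF-kB lists in 5 classes for the 3 main comparisons, with 95% counting intervals as bars and the central 95% of 10000 matched random lists in grey. In monocyte-like cells the interferon medians of Butyrate against Control (0.45) and B12+Butyrate against B12 (0.30) lie above the grey range.

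B12+Butyrate against B12 asked what butyrate water did on top of B12. The B-lineage-like share was 14.2% (13.4 to 15.1%) with both and 6.96% (6.39 to 7.56%) with B12 alone, a ratio of 2.05 (1.85 to 2.26), and myeloid-like classes were 81.2% (80.2 to 82.1%) against 89.7% of myeloid-like plus lymphoid-like cells. Wfdc17 in neutrophil-like cells was at 21.2 (20.04 to 22.5) CPM against 100.5 (97.9 to 103), and Ifitm1 at 39.4 (37.8 to 41.1) against 105 (103 to 108). Vcan, the proteoglycan versican of classical monocytes, was at 113 (108 to 118) CPM in monocyte-like cells against 273 (266 to 280.4). The interferon response list in monocyte-like cells had a median of 0.30 (interval 0.25 to 0.35), with 23 of 23 members higher, above all 10000 random lists.

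Neutrophil-like cells were 55.8% (54.7 to 57.0%) against 57.5% (56.4 to 58.6%), monocyte-like cells 14.2% (13.4 to 15.04%) against 18.1% (17.3 to 19.0%) and T-like cells 2.499% (2.15 to 2.89%) against 1.97% (1.67 to 2.31%). HSC/MPP-like cells were 1.02% (0.804 to 1.29%) against 1.71% (1.43 to 2.03%) of all cells and 20.8% against 25.2% of HSC/MPP-like plus GMP-like cells. GMP-like cells were 3.90% (3.46 to 4.38%) against 5.09% (4.60 to 5.61%) and plasmacytoid-DC-like cells 0.590% (0.425 to 0.796%) against 0.281% (0.174 to 0.429%). With the unnamed cluster nearest to plasmacytoid DCs the last were 2.48% and 2.32%, so that gap rests on where the class was bounded. With each library clustered alone the log2 share ratio was −0.78 for neutrophil-like (−0.04 here), −0.23 for monocyte-like (−0.35) and −0.26 for myeloid-like cells (−0.14). The neutrophil-like ratio was 0.02 with a looser cell filter, and the interferon median was 0.11 with the same makeup of monocyte clusters in each library.

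Olfm4 in neutrophil-like cells was at 164 (160.3 to 167) CPM with both treatments against 426 (421 to 431) with B12 alone. Cpa6, which encodes a carboxypeptidase (log2 0.41), the collagenase Mmp8 (0.39) and the formyl peptide receptor Fpr2 (0.37) were higher; Mmp8 and Fpr2 lead some of the neutrophil clusters. The primary granule list was lower in 6 of 7 members with a median of −0.64 (interval −0.70 to −0.57), with the protease gene Prtn3 at 166 against 293 CPM. Prtn3 was highest in GMP-like cells (8523 CPM), and the GMP RNA Elane was at 208 against 346 CPM in neutrophil-like and 8.07 against 19.8 in B-lineage-like cells. Tertiary granule genes were at −0.01 and secondary granule genes at 0.03. S phase was lower in 16 of 17 members (−0.10) and G2/M phase in 18 of 20 (−0.11), and both were near 0 (0.0028 and −0.0076) with the same makeup of neutrophil clusters. NF-kB genes were at −0.07 and interferon genes at −0.02.

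In monocyte-like cells Cmss1 (log2 0.56), Ldlrad3 (0.55) and the interferon-induced DNA sensor family member Ifi203 (0.51) were higher. Lcn2 (−0.98) and the calmodulin kinase gene Camk2d (−0.66) were lower. Ifi27l2a of the interferon list was at 0.46, and MHC class I presentation had a median of 0.15 with B2m at 1386 against 1098 CPM. All 20 G2/M members were lower, with a median of −0.34 (interval −0.37 to −0.30) and the survivin gene Birc5 at −0.47. S phase was at −0.11 (0.025 with the same makeup of monocyte clusters), NF-kB at −0.11 with 12 of 16 members lower, Toll-like receptor sensing at −0.05 and MHC class II at −0.12, or 0.19 at a clustering resolution of 2. The handling list was at −0.01.

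In B-lineage-like cells Jchain, the joining chain of secreted antibodies, was at 113 (104 to 122) CPM with both treatments and had 0 UMIs in B12. Against the floor of 3 UMIs in the B12 library (1.29 CPM) it was at least 87.2-fold higher, but its log2 ratio was −1.31 with doublets kept. Jchain was highest in plasma-like cells (23059 CPM), so a few plasma cells within the B-lineage-like class are not excluded as its source. Insyn2b (0.78) and Nopchap1 (0.67) were higher, and Tex14 (−1.50), S100a8 (−1.16) and Arrdc3 (−1.09) lower. MHC class II presentation was higher in 9 of 10 members with a median of 0.17 (interval 0.12 to 0.19). All 17 G2/M members were lower (−0.62), as were 14 of 16 handling genes (−0.22) and 9 of 13 interferon genes (−0.25), and NF-kB genes were at −0.18, or 0.033 with no minimum for list members.

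In GMP-like cells Ltf (0.75), Neat1 (0.55) and Tex14 (0.53) were higher, and Tex2 (−0.51), Txndc11 (−0.40) and the glycosyltransferase gene Mgat5 (−0.39) lower. With doublets kept the value of Ltf was 0.21. The unfolded protein response list was lower in 12 of 13 members with a median of −0.17 (interval −0.19 to −0.13). Handling (0.08, or −0.047 with cells thinned to 2000 UMIs), NF-kB (−0.08), interferon (0.03) and myeloid regulator genes (−0.05) had small medians. In HSC/MPP-like cells HSC identity genes were lower in 9 of 11 members with a median of −0.17 (interval −0.37 to −0.12) and Mecom at 197 against 296 CPM. That library held 73 HSC/MPP-like cells. The medians of NF-kB (0.04), interferon (0.06), handling (0.00), lymphoid (−0.02) and myeloid regulators (0.06) were small there, while secondary granule genes, which are neutrophil RNAs, were at 1.39.

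B12+Butyrate against Butyrate gave the B12 difference a second time, on butyrate water and from 2 libraries that the first does not use. Neutrophil-like cells were 55.8% against 41.3%, a ratio of 1.35 (1.31 to 1.40), and T-like cells 2.499% against 5.16%, a ratio of 0.485 (0.405 to 0.580). Monocyte-like cells had a ratio of 0.822 (0.760 to 0.889) and B-lineage-like cells of 0.943 (0.869 to 1.02). HSC/MPP-like cells had a ratio of 0.490 (0.369 to 0.651) of all cells and 0.530 (0.416 to 0.676) of HSC/MPP-like plus GMP-like cells, against 1.11 (0.867 to 1.41) and 0.907 (0.734 to 1.12) without butyrate. The myeloid share of myeloid-like plus lymphoid-like cells was 81.2% against 75.2%. Its log2 ratio of 0.11 was smaller with each library clustered alone. With each library clustered alone the log2 share ratio was −0.30 for neutrophil-like cells in place of 0.44 and 0.40 for monocyte-like cells in place of −0.28. That of B-lineage-like cells was 0.28 in place of −0.084.

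All 18 S phase members were higher in monocyte-like cells of B12+Butyrate than of Butyrate, with a median of 0.26 (interval 0.22 to 0.30) and Dut at 0.50. MHC class II genes were at 0.34 with H2-Aa at 0.59, but at −0.35 at a clustering resolution of 2 and −0.0049 with no minimum for list members. Olfm4 in neutrophil-like cells was at 164 against 141 CPM, a smaller gap than the one without butyrate. Of the other genes named there for B12 over Control, H4c4 (log2 −0.0013), Hspa5 (−0.10) and Retnlg (0.52) changed sign. Mpo (−0.49) and Suco (−0.04) did not. In HSC/MPP-like cells HSC identity genes were lower in 9 of 10 members, with a median of −0.44 (interval −0.57 to −0.31) and Hlf, a transcription factor of stem cells, at 82.7 against 187 CPM. Lymphoid regulators were at −0.38 (interval −0.53 to −0.31), with Dntt at −1.37. Secondary granule genes, which are neutrophil RNAs, were at 2.66 in the same HSC/MPP-like cells. NF-kB genes were lower in 11 of 12 members in GMP-like cells (−0.29) and in 13 of 15 in monocyte-like cells (−0.13). Several genes named for B12 over Control did not repeat here. In GMP-like cells Hspa1b (−0.28), Hspa1a (−0.57), Vcam1 (−0.29) and Ltf (0.76) changed sign, while Neat1 (−0.44) and Lars2 (−0.75) did not. In monocyte-like cells Hspa1b (0.06), Hspa1a (−0.01), Chil3 (0.11) and S100a9 (0.07) were nearly level, with Ctsg at 0.97 and Pde4b at −0.36. In B-lineage-like cells Tex14 (−0.10), Arrdc3 (−0.23), Apoe (0.20) and Nopchap1 (0.13) changed sign, while H2ac6 (1.01) and Il5ra (−0.14) did not.

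Across genes, the butyrate difference with B12 correlated with that without B12 at a Pearson r of 0.27, 0.56, −0.06, 0.42 and −0.16 in neutrophil-like, monocyte-like, B-lineage-like, GMP-like and HSC/MPP-like cells, with Spearman rho of 0.00, 0.48, −0.03, 0.44 and 0.04. For the B12 difference in both waters r was −0.07, 0.46, 0.06, 0.21 and 0.13 and rho −0.15, 0.45, −0.01, 0.23 and 0.25. These pairs share no library. Genes are not independent replicates, and 15 correlations were computed. Monocyte-like cells had the highest r in both pairs, over 3592 genes. The B12 difference and the difference made by adding butyrate to B12 use the same B12 library with opposite signs, and r was −0.41, −0.42, −0.71, −0.27 and −0.31. Counts drawn with no difference between libraries gave −0.47, −0.49, −0.69, −0.46 and −0.45. The covariance in monocyte-like cells was −0.00928, against −0.000775 from such counts. Any other departure of the shared B12 library also makes these values negative. They therefore cannot tell whether butyrate reversed the B12 difference.

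**Figure D4:**
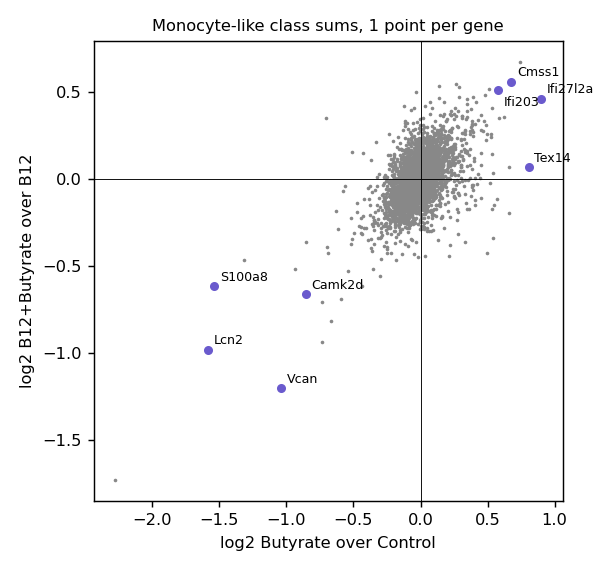
Each point is a gene in monocyte-like cells, with its log2 ratio of Butyrate over Control on the horizontal axis and of B12+Butyrate over B12 on the vertical axis. Across genes r was 0.56, and Vcan, Lcn2 and Camk2d lie low and Ifi27l2a, Cmss1 and Ifi203 high on both axes.

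Over the 5 classes and 3 main comparisons, medians of lists aimed at the treatments themselves ran from −0.10 to 0.11 for B12 and one-carbon metabolism, −0.31 to 0.11 for DNA methylation machinery, −0.12 to 0.06 for histone deacetylases and −0.15 to 0.14 for butyrate receptors and transporters. The lowest, of DNA methylation machinery, was that of B-lineage-like cells for B12+Butyrate against B12 (−0.31 (interval −0.40 to −0.05), 5 of 8 members lower). Of 15 medians each, 1, 1, 0 and 2 lay outside the central 95% of the random lists. Over all lists and classes 115 of 356 medians did so.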

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

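Class shares and the list medians chosen for description were searched for opposite signs between backgrounds, and single genes were not. Each pair of values below went 1 way in 1 background and the other way in the other, with counting intervals clear of 0 on both sides. List medians also had to lie outside the random lists in both. None of these differences was tested, since each group is 1 library, and all were picked out after the values were seen. Intervals of single libraries leave out variation between mice, and those of list medians also variation between cells. Opposite signs of this size therefore carry no replicate check.

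Within that search the B12 difference had opposite signs on sodium chloride and on butyrate water for 6 list medians (log2). In neutrophil-like cells these were the tertiary granule and maturation list (−0.081 and 0.17), S phase (0.063 and −0.20) and G2/M phase (0.056 and −0.089). With the same makeup of neutrophil clusters in each library they were −0.0075 and 0.023, 0.013 and −0.015, and −0.046 and −0.0017, so the opposite signs of G2/M phase were gone and the other gaps were smaller. In monocyte-like cells they were G2/M phase (0.071 and −0.18) and the handling list of immediate early and heat shock genes (0.069 and −0.13). The G2/M phase values had the same sign with standardised makeup (−0.13 and −0.21) and at resolution 2 (−0.035 and −0.12). In GMP-like cells they were the myeloid lineage regulators (0.088 and −0.16). The median of secondary granule genes in HSC/MPP-like cells, given above, also changed sign and is not counted here.

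Within that search the butyrate difference had opposite signs without and with B12 for 4 values. The log2 ratio of the HSC/MPP-like share of all cells was 0.43 without B12 and −0.74 with it. In neutrophil-like cells S phase was at 0.11 and −0.10, and G2/M phase at 0.036 and −0.11. With the same makeup of neutrophil clusters these were 0.038 and 0.0028 for S phase and −0.047 and −0.0076 for G2/M phase, with no opposite signs left. In B-lineage-like cells the handling list was at 0.32 and −0.22. Not among the values counted were secondary granule genes in HSC/MPP-like cells (−1.82 and 1.39) and single genes such as Ltf in GMP-like cells (−0.73 and 0.75).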

How the results depend on the processing

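The alternatives without the interferon-high monocyte cluster and with the cluster nearest to plasmacytoid DCs were chosen after the data were seen; the others were planned. Across all alternatives 9 of 196 share ratios, 85 of 1244 list medians, 2 of 648 named gene ratios and 1 of 20 correlations changed sign. Of these, 3, 20, 2 and 0 had a first value whose interval (0.1 to each side for correlations) left out 0, and for lists that also lay outside the random lists. Apart from those, 29, 226, 188 and 1 values left their interval. Values below are log2, and the cause was not tested for any of them. No paired analysis was possible because each group is 1 library. With each library clustered alone there was no HSC/MPP-like ratio, because that class stayed unnamed in 3 libraries.

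Clustered alone, the neutrophil-like share ratio was −0.78 for B12+Butyrate over B12 and −0.30 for B12+Butyrate over Butyrate. The monocyte-like ratio was −0.60 (B12 over Control), −1.22 (Butyrate over Control), −0.23 (B12+Butyrate over B12) and 0.40 (B12+Butyrate over Butyrate). The B-lineage-like ratio was 0.17 (Butyrate over Control) and 0.28 (B12+Butyrate over Butyrate). Myeloid-like classes were at −0.17, −0.26 and 0.039 in the last 3 comparisons. The T-like ratio kept its direction under every alternative run in both B12 comparisons.

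Under the looser filter the neutrophil-like ratio was 0.020 for B12+Butyrate over B12 and 0.49 over Butyrate, the B-lineage-like ratio −0.25 for B12 over Control and 0.78 for B12+Butyrate over B12, and Apoe in B-lineage-like cells 0.19 for B12 over Control. Under the stricter filter the same B-lineage-like ratios were −0.85 and 1.22, the neutrophil-like ratio over Butyrate 0.38 and the myeloid-like ratio of Butyrate over Control −0.096. With doublets kept the neutrophil-like ratio was 0.47 for B12 over Control and −0.085 for B12+Butyrate over B12, Jchain in B-lineage-like cells −1.31 for the latter, and G2/M phase in B-lineage-like cells 0.12 for Butyrate over Control and −0.17 for B12+Butyrate over Butyrate.

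At resolution 0.5 the HSC/MPP-like ratio among HSC/MPP-like plus GMP-like cells was −0.45 and HSC identity 0.24 for B12 over Control, and G2/M phase in B-lineage-like cells −0.0094 for B12+Butyrate over Butyrate. At resolution 2 the monocyte-like ratio was −0.12 (Butyrate over Control) and −0.54 (B12+Butyrate over Butyrate). In monocyte-like cells it gave −0.18 (B12 over Control) and 0.42 (B12+Butyrate over B12) for interferon genes, 0.17 (Butyrate over Control) for NF-kB genes, −0.035 (B12 over Control) for G2/M phase, and −0.42 (B12 over Control) and −0.35 (B12+Butyrate over Butyrate) for MHC class II. With the nearest unnamed cluster added, the plasmacytoid-DC-like ratio was −0.83 for B12 over Control and 0.10 for B12+Butyrate over B12. Other variable genes gave monocyte-like ratios of −0.44 (B12 over Control) and −0.43 (B12+Butyrate over Butyrate) and a myeloid-like ratio of 0.15 (B12 over Control).

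With standardised cluster makeup the interferon median in monocyte-like cells was 0.081, 0.31 and 0.11 for B12 over Control, Butyrate over Control and B12+Butyrate over B12. NF-kB was 0.023 in the first and −0.17 in the last, G2/M phase −0.13 in the first and S phase 0.025 in the last. In neutrophil-like cells G2/M phase was −0.046 (B12 over Control) and −0.047 (Butyrate over Control), tertiary granule genes 0.023 (Butyrate over Control) and S phase 0.0028 (B12+Butyrate over B12). Without the interferon-high cluster the interferon median was 0.040 (B12 over Control) and 0.16 (B12+Butyrate over B12).

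With a pseudocount of 1 the same interferon medians were −0.15, 0.59 and 0.44. Thinned cells gave −0.0046 for the interferon and 0.050 for the NF-kB median (B12 over Control), −0.23 for NF-kB (B12+Butyrate over B12), and in GMP-like cells −0.003 for myeloid regulators (Butyrate over Control) and −0.047 for the handling list (B12+Butyrate over B12). With no minimum for members NF-kB was −0.076 in monocyte-like cells (B12+Butyrate over B12), −0.032 (B12 over Control) and 0.033 (B12+Butyrate over B12) in B-lineage-like cells, and MHC class II −0.0049 in monocyte-like cells (B12+Butyrate over Butyrate).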

Other observations

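The tests named below on the sort mix, the quality filter, mouse pools, free monocyte RNA and handling stress were chosen after the results were seen; those on neutrophil makeup and the interferon-high cluster were set before their values were seen. Shares of the smaller classes rest on few cells. In Control, Butyrate, B12 and B12+Butyrate, plasma-like cells were 0.211%, 0.126%, 0.0268% and 0.0140% of all cells (17, 8, 2 and 1 cells). Basophil-like cells were 0.656%, 0.377%, 0.576% and 0.393% (53, 24, 43 and 28 cells). NK-like cells were 0.520%, 0.770%, 0.482% and 0.758% (42, 49, 36 and 54 cells). Counting error covers several of these gaps, as for NK-like cells of B12 over Control (ratio 0.926, interval 0.594 to 1.44). Cholesterol synthesis genes were lower with B12 in neutrophil-like cells (median log2 −0.13, 9 of 9 members lower) and higher when butyrate was added to B12 (0.17, 8 of 9 higher). In monocyte-like cells oxidative phosphorylation was at −0.09 and −0.14 and glycolysis at −0.09 and −0.15 in the butyrate comparisons without and with B12, each with most members lower.

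Over the 5 classes and 3 main comparisons the medians of oxidative stress genes ran from −0.10 to 0.06, of p53 targets from −0.19 to 0.14 and of megakaryocyte and erythroid regulators, measured in HSC/MPP-like cells, from −0.06 to 0.08. Haemoglobin was near absent, with Hba-a1 at 1.18, 1.38, 1.70 and 1.60 CPM, and Xist was at 915, 998, 848 and 816 CPM over all cells.

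More neutrophil-like and fewer T-like cells with B12 could come from the mix of Kit+ and Kit- sorts. On butyrate water the neutrophil-like increase is not settled, as its log2 ratio was −0.30 with each library clustered alone in place of 0.44. A change in that mix moves T-like and B-lineage-like cells alike. Yet the log2 ratio of the T-like over the B-lineage-like change was −0.73 (interval −1.04 to −0.41) on sodium chloride water. On butyrate water it was −0.96 (interval −1.25 to −0.67). These values argue against the mix as the whole cause of fewer T-like cells. The neutrophil-like increase was not part of that test, so the mix stays open for it. Loss at the quality filter is argued against for the neutrophil-like increase of B12 over Control. Its log2 ratio was 0.36 under the looser filter (0.49 for B12+Butyrate over Butyrate). The T-like share was not part of that test, though its ratio kept its direction under every alternative run. Differences between pools of mice cannot be told apart from B12, with 1 library per group, and B12 itself stays open and untested.

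Lower Wfdc17 and Ifitm1 in neutrophil-like cells of both butyrate libraries could come from less free RNA of monocytes, in which Wfdc17 is higher. At the median level of the monocyte markers in neutrophil-like cells, such RNA would bring a share of 0.0246 (interval 0.0221 to 0.0271) of their Wfdc17 UMIs in Control. In B12 that share was 0.0126 (interval 0.0108 to 0.0143), and it was smaller for Ifitm1 in both libraries. This argues against such RNA at that median level. The ratios of single markers in Control ran from 0.0014 (Fn1) to 0.53 (Ly6c2), a spread that the intervals leave out. With the same makeup of neutrophil clusters in each library Wfdc17 was still at −1.32 (interval −1.41 to −1.23) and −1.78 (interval −1.87 to −1.70). In the class sums the values were −1.74 for Butyrate over Control and −1.82 for B12+Butyrate over B12. Class sums weight clusters by UMIs and the standardised values by cells, so the gap between them is not the effect of makeup alone. The standardised values argue against fewer mature neutrophils as the whole cause of lower Wfdc17. Ifitm1 was not part of that test. Within the neutrophil cluster with the highest score for mature neutrophil markers Wfdc17 was at 2459, 978, 2526 and 691 CPM in Control, Butyrate, B12 and B12+Butyrate. Ifitm1 was at 2905, 1302, 2405 and 1138 CPM there. In the other mature cluster, led by Retnlg and Mmp8, Ifitm1 was at 267, 108, 257 and 84.9 CPM. These values argue against fewer cells of those clusters as the whole cause of lower Ifitm1. Butyrate and differences between pools of mice both stay open.

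Higher interferon genes in monocyte-like cells of both butyrate libraries could come from more cells of the interferon-high cluster. Without it the median was 0.38 (interval 0.31 to 0.41) for Butyrate over Control, which argues against that cluster as the whole cause there, and it was 0.16 (interval 0.13 to 0.23) for B12+Butyrate over B12, where the cluster's part cannot be told apart; the test was written for both comparisons together, and so read it leaves the cluster open. Stress of handling stays open for Butyrate over Control, where the handling genes had a median of 0.32 (central 95% of members −0.21 to 0.62). For B12+Butyrate over B12 their median was −0.00881 (central 95% −0.32 to 0.16), under the interferon median of 0.30. That bound was set after the values were seen. The interferon median was 0.16 without the interferon-high cluster, within the range of the handling genes, and lower still with the same makeup of monocyte clusters. Handling stress is therefore not settled there either. Butyrate stays open as an untested explanation.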
